A study of Mus musculus with 96 samples.

How the data were processed

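Per the labels, all 96 libraries came from mouse striatum that had received an adeno-associated virus. Per the labels, each group of mice gave input libraries and IP libraries of polyA RNA. The labels name neither the virus cargo nor the protein or tag used for the immunoprecipitation. Per the labels, RNA was purified with a column kit that also removes DNA, and libraries were made with a TruSeq kit. Per the labels, the Q175 and WT libraries share 1 run label. The R6/2 and NCAR libraries carry another at 1 month and a further label at 2 and 3 months, so that age and run cannot be told apart at 1 month. The labels give no sex, no batch below the run label, and no tie between an IP library and an input library. Replicates of a group are numbered here in the order of the labels.

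Per the submitters' processing notes, reads were aligned with STAR to mm10 and counted with HTSeq. The same notes name edgeR and limma as the submitters' tools for values and tests, with no version for any of them. Strand use of the counting is not stated in the labels. The deposited values are log2 CPM, 1 table for each run label with 15652, 15648 and 15905 genes. Of these, 15262 symbols were in all 3 tables. The symbols March1 and March2 were listed more than 1 time and were left out. How the authors chose the genes kept in each deposited table is not stated. The lowest CPM reached in at least 4 libraries of a table was 0.528, 0.444 and 0.224 over the 3 tables. Blood genes other than Alas2 and the X-linked Xist were not in the deposited tables used here.

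Read counts were recovered from the deposited log2 values. A prior of 0.25 reads gave whole numbers within 0.01 for 100% of values in each of the 96 libraries. The recovered totals were 27.12 to 84.21 M reads per library, with a median of 54.7 M in IP and 34.78 M in input. The Q175 table was scaled by read totals alone. In the R6/2 tables the scaled library size was 0.814 to 1.214 times the read total.

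The design fixed before the data were examined named a quasi-likelihood count test, which assumed that counts were deposited. The deposited unit was log2 CPM, and limma 3.58.1 with an intensity trend was used instead of that edgeR test, which was not run on the recovered reads either. It was run in R 4.3.3 on log2 CPM computed again from the recovered reads. Scaling was by the trimmed mean of M values (TMM) within each fit, trimming 30% of M and 5% of A values, with a prior count of 0.25. Genes were kept at 10 reads in a library of median size in at least the number of libraries of the smallest group, and at least 15 reads in total. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Each of 12 genotype comparisons was fitted alone with 4 libraries per group, by age and RNA type. IP was tested against input in the 6 control groups. There were 4 interaction tests, genotype by RNA type at 12 months in Q175 and at 3 months in R6/2, and genotype by age in IP, 12 against 2 months in Q175 and 3 against 2 months in R6/2.

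Named genes followed a fixed rule. Htt came before all others. In each genotype comparison the rule took the 10 highest and 10 lowest fold changes in IP, or 5 and 5 in input. They were taken among called genes with a mean of at least 5 CPM and no overlap between the libraries of the genotypes. The 8 highest and 4 lowest genes were taken for IP against input, and 5 and 5 for the interactions. Symbols of the form Gm or LOC plus digits and those ending in Rik were passed over. Up to 4 members with the smallest p were taken from each gene list. Some genes that the rule takes are not described here. CPM levels are means with SD over 4 libraries and use the scaling of the comparison described. Levels of Htt and of gene lists by group, and of Rpl22 where all groups are given, use 1 scaling over all libraries of a run. A gene was IP-enriched at a log2 IP over input of at least 1 with an adjusted p under 0.05 in the control mice of the other 2 ages of its cohort.

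The 21 gene lists were astrocyte markers, medium spiny neuron, pan-neuronal, oligodendrocyte lineage, microglia, endothelial and mural, ependymal and choroid plexus, blood, pan-reactive, A1 and A2 reactive astrocyte, cholesterol synthesis and uptake, astrocyte transport and buffering, calcium and G protein-coupled receptor signalling, matrix and synapse-regulating factor, glucose and lactate metabolism, nuclear oxidative phosphorylation, immediate early, chaperone, developmental patterning transcription factor, and interferon response genes. Members were counted as called over all genes tested and over the list alone. Lists were tested with limma camera at a preset correlation of 0.01 and adjusted over the lists of a comparison. The correlation was also estimated from the data. The blood list held at most 1 measured member, Alas2, and was not tested as a list. Overlaps between comparisons were set against n1 x n2 / N, the number that independent lists would share, and tested with the one-sided Fisher exact test.

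Gene positions came from GENCODE M21 on the mm10 assembly. Of 16221 symbols, 15422 matched 1 gene directly, 616 matched through an older symbol and 183 were not matched. Abhd1, Htt, Crb2, Chdh, Nrn1, Cxcl10, Pla2g5, Col9a3 and Abhd11os are among the genes named below that overlap another annotated gene, so that their reads and those of the neighbor are not fully separate. Members of the Gbp, Tgtp, H2 and Pcdhb families share long stretches of sequence.

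The alternatives set before the data were examined were median-of-ratios factors, no filter on low counts, limma voom, an adjusted p under 0.10, each library left out in turn, all ages of a run in 1 fit, a pan-neuronal covariate and other IP-enrichment thresholds. A test with DESeq2 was not run on the recovered reads either, so that voom was the alternative that models the spread of reads. A covariate for sex was not run because Xist was not in the tables used here. The Y-linked genes Ddx3y and Uty stood at 60.34 and 32.11 CPM or more in every library. Figures and read recovery used python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

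The power of the tests was measured by changing 200 genes at known folds in data simulated from the spread of each comparison. The changed genes had a mean of at least 5 CPM, so the shares do not cover lower genes. Reads were drawn for each gene alone, so differences that many genes of a library share were not simulated. At a true change of 2-fold, 97% of changed genes were called for IP of Q175 at 2 months. The same share was 82.1%, 73.1% and 79.1% for IP of R6/2 at 1, 2 and 3 months. At 1.5-fold it was 28.4% for IP of R6/2 at 2 months and 26.9% for the genotype by age test in R6/2. For genotype by RNA type it was 46.3% in Q175 and 13.4% in R6/2.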

Results

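RNA from mouse striatum was sequenced in 2 models of Huntington's disease and their controls. Q175 mice carry an expanded CAG repeat in the mouse Htt gene and were compared with WT at 2, 6 and 12 months of age. R6/2 mice carry a fragment of human HTT as a transgene and were compared with NCAR controls at 1, 2 and 3 months. Each of the 24 groups had 4 libraries of either input RNA, which is RNA of the whole tissue, or IP RNA, which is RNA recovered by immunoprecipitation. The 48 IP libraries held 41.87 to 84.21 M reads and the 48 input libraries 27.12 to 51.19 M reads. Levels below are in CPM (reads of a gene relative to library size), mean ± SD over 4 libraries, and changes are log2 fold changes ± SE of limma fits. No label states that the libraries of a group came from separate mice, so p-values of limma fits measure only the spread between these libraries. Genes are ranked only among called genes with a mean of at least 5 CPM over the libraries compared, for genotype with no overlap between the libraries of the genotypes, and without symbols of predicted genes. Genes below that level or with overlap had higher or lower changes in some comparisons. Genes shared between the 2 models were taken by adjusted p, without the bounds on level and overlap.

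Htt, the huntingtin gene (chr5 34761740 to 34912534, mm10), was lower in IP RNA of Q175 mice at every age. In IP it stood at 284 ± 8.13 CPM in Q175 against 377 ± 6.05 in WT at 2 months, 310 ± 19.2 against 386 ± 10.1 at 6 months, and 288 ± 15.5 against 408 ± 32.0 at 12 months. The log2 changes were -0.39 ± 0.04, -0.31 ± 0.06 and -0.49 ± 0.07 (adjusted p = 0.00959, 0.0145 and 0.00369). In input RNA Htt stood at 192 ± 9.29 CPM against 234 ± 9.17, 191 ± 15.7 against 241 ± 11.4, and 174 ± 16.1 against 232 ± 21.3. The input change was called at 6 and 12 months, at -0.32 ± 0.06 and -0.41 ± 0.08 (adjusted p = 0.00802 and 0.00342), and not at 2 months, at -0.28 ± 0.04 (adjusted p = 0.163). The sign held in Q175 without any single library.

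In R6/2 mice, whose own Htt gene is unaltered, Htt was not called at any age. IP levels in R6/2 and NCAR were 302 ± 6.40 and 255 ± 27.9 CPM at 1 month, 322 ± 67.1 and 320 ± 17.9 at 2 months, and 362 ± 97.1 and 335 ± 33.8 at 3 months. Input levels were 244 ± 2.53 and 249 ± 13.0, 213 ± 7.97 and 254 ± 36.7, and 200 ± 20.9 and 215 ± 14.4 CPM. Adjusted p was 0.242, 0.98 and 0.823 in IP and 0.825, 0.152 and 0.333 in input.

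**Figure D1:**
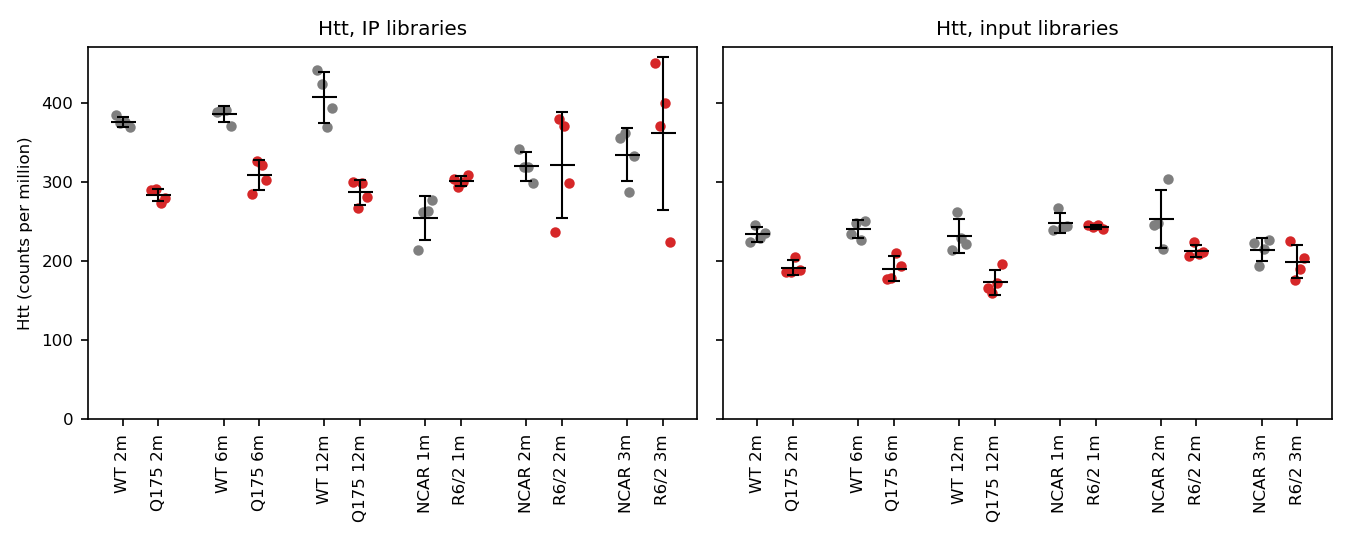
Htt in CPM in each IP library (left) and input library (right), by genotype and age. Points are libraries, 4 per group, and bars are mean ± SD; Q175 IP at 12 months stood at 288 ± 15.5 against 408 ± 32.0 in WT.

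IP RNA of control mice was rich in astrocyte transcripts. At 2 months in WT the highest ratios over input were those of Slc1a2, the main glutamate transporter of astrocytes (4.04 ± 0.10, 16.5-fold), Atp1b2, a sodium pump subunit (3.98 ± 0.08, 370 ± 43.8 against 23.3 ± 1.25 CPM), and Gli2, a Hedgehog pathway factor (3.97 ± 0.24). They were followed by the potassium channel Kcnj10 (3.76 ± 0.10), the nuclear receptor Rorb (3.71 ± 0.08), the Hippo pathway factor Tead1 (3.69 ± 0.10), the glial factor Sox9 (3.66 ± 0.10) and the secreted Thbs4 (3.62 ± 0.18). The lowest ratios were those of small structural RNAs and microglial genes. Rmrp, the RNA of RNase MRP, stood at -7.09 ± 0.18, Snora74a, which guides RNA modification, at -6.43 ± 0.30, the microglial adaptor Tyrobp at -6.14 ± 0.37 and the lysozyme Lyz2 at -5.67 ± 0.32. Htt was 1.59-fold higher in IP than in input at this age (adjusted p = 8.24e-08).

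All 30 measured astrocyte markers were called higher in IP in WT at 12 months, with a median of 2.05 (adjusted p = 3.7e-14, and adjusted p = 0.0213 with an estimated correlation). All 18 astrocyte transport and buffering genes were higher as well, among them Gja1, which forms gap junctions (2.47 ± 0.05), and Kcnj10 (3.50 ± 0.11). Interferon response genes had 13 of 15 members up (median 1.38), cholesterol genes 23 of 23 (0.92) and oligodendrocyte genes 15 of 20 up and 1 down (0.63), and as lists these 3 passed only at the preset correlation (adjusted p = 0.387, 0.226 and 0.365 with an estimated correlation). All 15 microglia genes were lower (median -4.67, adjusted p = 1.42e-09, adjusted p = 0.205 with an estimated correlation), as were 14 of 15 endothelial and mural genes (-2.72, adjusted p = 0.205 with an estimated correlation). Medium spiny neuron genes were lower for 22 of 24 members (-0.85, adjusted p = 0.387 with an estimated correlation), whereas pan-neuronal genes were higher for 15 and lower for 6 of 24 members (0.37). Chat, the acetylcholine enzyme (1.83 ± 0.06), and Nos1, the neuronal nitric oxide synthase (2.76 ± 0.09), were both higher in IP. Oxidative phosphorylation genes had 12 members up and 10 down, and their median of 0.04 and mean of -0.02 differ in sign.

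The other control groups gave similar top genes. Atp1b2 was at 3.35 ± 0.09 and 3.91 ± 0.14 in WT at 6 and 12 months and at 4.09 ± 0.10, 3.76 ± 0.33 and 3.48 ± 0.23 in NCAR at 1, 2 and 3 months, and Slc1a2 at 3.22 ± 0.13, 3.22 ± 0.13, 4.26 ± 0.06, 3.65 ± 0.23 and 3.36 ± 0.25. In WT at 6 months the list also held the filament gene Gfap (3.05 ± 0.19) and the factor Tfcp2l1 (2.98 ± 0.08), and at 12 months Gpc4, a surface proteoglycan (3.27 ± 0.21), the interferon-induced GTPase Gbp5 (3.15 ± 0.21) and Igfbp5 (3.13 ± 0.16). In NCAR it held Mir6236 (6.07 ± 0.36), Dmp1 (4.21 ± 0.19) and Arhgef26 (4.01 ± 0.11) at 1 month, Cd109 (3.71 ± 0.32) at 2 months and the protease inhibitor A2m (3.17 ± 0.62) at 3 months. Rmrp was lowest or next to lowest everywhere, at -7.51 ± 0.16, -7.54 ± 0.10, -7.82 ± 0.14, -7.87 ± 0.61 and -6.86 ± 0.38. Htt was higher in IP in each group, at 0.69 ± 0.05, 0.83 ± 0.08, 0.33 ± 0.11 and 0.65 ± 0.10, except in NCAR at 1 month (0.02 ± 0.08, adjusted p = 0.816).

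Between IP and input 12250, 11935 and 11974 genes were called in WT at 2, 6 and 12 months and 11146, 8554 and 8715 in NCAR at 1, 2 and 3 months, of 15326 to 15560 tested. Scaled as deposited, without TMM, the share of calls that were higher was 34.6%, 31.9% and 33.3% in WT against 48.7%, 48.7% and 49.2%, and the median of all genes was -0.27, -0.28 and -0.26 against -0.03, -0.02 and -0.01.

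At 2 months Q175 IP RNA differed from WT in 3 genes. Abhd1, a hydrolase-like gene on the chromosome of Htt (chr5 30950066 to 30955091), was 4.72-fold higher at 13.9 ± 1.61 against 2.94 ± 0.341 CPM (2.24 ± 0.11, adjusted p = 3.68e-05). Htt was lower, and the other called gene is not described here. Of 15038 genes tested, 749 had an unadjusted p under 0.05, where 752 would be reached by chance. No member of any gene list was called. Over the list alone, 4 of 15 microglia genes were higher (median 0.57, adjusted p = 1.41e-10 by camera, adjusted p = 0.211 with an estimated correlation) and 2 of 24 medium spiny neuron genes were lower (median -0.14, adjusted p = 5.75e-11, adjusted p = 0.451 with an estimated correlation). The count was 7 without Q175 replicate 3, 1 without Q175 replicate 4 or without WT replicate 1, and 8 when all ages were fitted together.

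By 6 months 574 of 15121 genes were called in Q175 IP RNA, 49 higher and 525 lower. Ryr1, a calcium release channel (chr7 29003344 to 29125179), fell most of the genes ranked, to 8.44 ± 0.918 CPM from 42.7 ± 3.62 (-2.34 ± 0.09, adjusted p = 3.48e-06). Scn4b, a sodium channel subunit (chr9 45138395 to 45154152), fell to 242 ± 25.0 from 832 ± 54.3 CPM (-1.78 ± 0.08), and Penk, the enkephalin precursor (chr4 4133531 to 4138819), to 228 ± 36.3 from 676 ± 86.8 CPM (-1.57 ± 0.12). The matrix gene Abi3bp (-1.75 ± 0.12), the kinase Plk5 (-1.74 ± 0.12), the replication checkpoint gene Clspn (-1.58 ± 0.17) and the death-promoting Hrk (-1.57 ± 0.09) fell as well. The signalling genes Rgs14 (-1.42 ± 0.17) and Acvrl1 (-1.34 ± 0.12) and the myosin Myo3b (-1.31 ± 0.16) were the next. Adjusted p of these genes was at most 0.00178.

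The highest change at 6 months among the genes ranked was again that of Abhd1 (4.20-fold, 2.07 ± 0.14, adjusted p = 0.000118). Sfmbt2, a Polycomb-type gene, rose 1.85-fold (0.89 ± 0.08, adjusted p = 0.000407), followed by AW551984 (0.79 ± 0.13) and Vwa5b2 (0.65 ± 0.15, adjusted p = 0.0415), both with von Willebrand domains. The clustered protocadherins Pcdhb21 (0.59 ± 0.08) and Pcdhb16 (0.49 ± 0.08), the kinase-like N4bp2 (0.56 ± 0.10), the zinc finger gene Zbtb7c (0.54 ± 0.09), Car8, whose protein binds an inositol trisphosphate receptor (0.48 ± 0.08), and the repair ligase Rad18 (0.47 ± 0.09) rose too. Of medium spiny neuron genes 21 of 24 were lower, and 23 over the list alone (median -0.84, adjusted p = 2.51e-36, adjusted p = 0.157 with an estimated correlation). Calcium and receptor signalling genes had 5 of 28 members lower, among them the calcium channel Itpr1 (-0.90 ± 0.11), Plcb1 (-0.68 ± 0.10) and the glutamate receptor Grm5 (-0.69 ± 0.10), while the list median was 0.04 and its mean -0.07. Onecut1, a developmental factor, was called higher near the floor of detection. None of 30 astrocyte markers was called (median 0.07).

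The 6-month IP count was 305 without Q175 replicate 4, 333 without WT replicate 2, 356 without WT replicate 1, 371 without Q175 replicate 1, and 243 with a pan-neuronal covariate. Scaled as deposited it was 497 genes with 20.3% of calls higher, against 8.5%.

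At 12 months 1059 of 15190 genes were called in Q175 IP RNA, 334 higher and 725 lower. Dsp, a desmosome gene, rose 6.14-fold to 8.93 ± 1.13 CPM (2.62 ± 0.18, adjusted p = 9.95e-05), and Tmc3, a channel-like gene, rose 4.73-fold to 11.4 ± 1.55 CPM (2.24 ± 0.27). They were followed by Thsd1 (1.58 ± 0.34), the choline dehydrogenase Chdh (1.42 ± 0.16), the phospholipase Pla2g5 (1.32 ± 0.15), Enpp6, an enzyme of new oligodendrocytes (1.22 ± 0.13), titin (Ttn, 1.18 ± 0.22), the lipid flippase Atp10b (1.08 ± 0.15), the ectonucleotidase Enpp1 (1.07 ± 0.16) and Sfmbt2 (1.03 ± 0.12). Ryr1 fell to 6.74 ± 0.763 from 44.8 ± 4.62 CPM (-2.73 ± 0.10, adjusted p = 1.11e-06). Abi3bp (-2.34 ± 0.17), Scn4b (-2.16 ± 0.18), Hrk (-2.12 ± 0.14), the carbonic anhydrase Car12 (-1.86 ± 0.18) and Penk (-1.71 ± 0.19) fell with it. The last of the 10 lowest among the genes ranked were Acvrl1 (-1.67 ± 0.24), Clspn (-1.65 ± 0.18), Rgs14 (-1.63 ± 0.16) and the serotonin receptor Htr1b (-1.53 ± 0.14). Abhd1 stood at 2.19 ± 0.14 (adjusted p = 6.5e-05).

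Medium spiny neuron genes were lower for 23 of 24 members at 12 months (median -1.06, adjusted p = 7.52e-26, adjusted p = 0.408 with an estimated correlation), including the regulators Arpp21 (-1.24 ± 0.13) and Pde10a (-1.49 ± 0.17). Of 24 pan-neuronal genes only Nrgn, a calmodulin-binding gene, was called, at -0.91 ± 0.13 (median of the list -0.07). Immediate early genes had 4 of 14 members lower, 8 over the list alone, among them Egr1 (-1.26 ± 0.20) and Junb (-0.77 ± 0.16), with a median of -0.62 (adjusted p = 7.08e-06, adjusted p = 0.763 with an estimated correlation). Interferon response genes had 4 of 15 lower, 10 over the list alone, among them the ubiquitin-like Isg15 (-0.91 ± 0.17) and the antiviral Rsad2 (-0.65 ± 0.15), with a median of -0.35 (adjusted p = 2.05e-06, adjusted p = 0.763 with an estimated correlation). The cholesterol list had a median of -0.32 with 1 of 23 members lower and 4 over the list alone, Insig1, a brake on sterol synthesis, at -0.69 ± 0.14 (adjusted p = 1.32e-05 for the list, adjusted p = 0.819 with an estimated correlation). Of astrocyte markers Itih3 was lower (-0.58 ± 0.12) and 29 of 30 were not called. The potassium channel Kcnj16 (0.51 ± 0.09) and the synapse-promoting Thbs2 (0.96 ± 0.17) were each the only called member of the transport and matrix lists. Calcium and receptor genes had 5 of 28 lower, with a median of 0.06 and a mean of -0.03.

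The 12-month IP count was 460 without WT replicate 2, 571 without WT replicate 4, 608 without WT replicate 1, 657 without Q175 replicate 2, 1720 with an astrocyte marker covariate and 1865 with all ages in 1 fit. Scaled as deposited it was 1261 with 53.0% of calls higher, against 31.5%.

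In R6/2 IP RNA at 1 month 12 of 15119 genes were called, 2 higher and 10 lower. Titin (Ttn) rose 2.86-fold to 8.10 ± 1.06 CPM (1.51 ± 0.15, adjusted p = 0.0123). Ryr1 fell to 10.2 ± 2.45 from 33.4 ± 8.12 CPM (-1.71 ± 0.21, adjusted p = 0.0315), and Pde10a, the phosphodiesterase of medium spiny neurons (chr17 8525372 to 8986648), to 456 ± 45.8 from 881 ± 17.6 CPM (-0.95 ± 0.08, adjusted p = 0.00358). Foxj1, which drives cilia (-0.93 ± 0.12), Igfbp4 (-0.91 ± 0.13) and the deiminase Padi2 (-0.70 ± 0.10) were lower, as were the phosphatase regulators Ppp1r1b (-0.69 ± 0.09) and Ppp1r16b (-0.63 ± 0.07), the signalling regulator Rgs9 (-0.60 ± 0.08) and the receptor modulator Lynx1 (-0.55 ± 0.07). Over the list alone 14 of 24 medium spiny neuron genes were lower (median -0.44, adjusted p = 1.19e-17, adjusted p = 0.0796 with an estimated correlation), and 17 of 20 oligodendrocyte genes (median -0.68, adjusted p = 1.02e-15, adjusted p = 0.0796 with an estimated correlation). Calcium and receptor genes were lower as a list with either correlation (median -0.17, adjusted p = 1.12e-05 and 0.045), with 3 of 28 called over the list alone. This fall was not specific to that list. Astrocyte markers fell by a similar median (-0.16, adjusted p = 7.7e-06, adjusted p = 0.0796 with an estimated correlation) with 0 of 30 called by limma and 3 over the list alone, and transport and buffering genes by -0.25 (adjusted p = 1.18e-05, adjusted p = 0.0796 with an estimated correlation).

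The 1-month IP count was 34 without NCAR replicate 1, 2 without R6/2 replicate 1 or NCAR replicates 3 or 4, 3 without NCAR replicate 2, 4 without R6/2 replicate 4 and 6 without R6/2 replicate 3. It was 7 by voom, 19 with a pan-neuronal covariate and 0 with an astrocyte marker covariate, while 1799 genes had an unadjusted p under 0.05 in limma against 756 expected.

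At 2 months 842 of 15022 genes were called in R6/2 IP RNA, 168 higher and 674 lower. The activity-regulated factor Egr2 fell to 0.471 ± 0.187 from 15.3 ± 3.04 CPM (-5.07 ± 0.28, adjusted p = 8.68e-05) and Ryr1 to 4.51 ± 1.25 from 50.2 ± 7.92 CPM (-3.50 ± 0.21). The coreceptor Cd4 (-2.83 ± 0.24), Penk (-2.72 ± 0.25), Scn4b (-2.65 ± 0.26), the orphan receptor Nr4a1 (-2.54 ± 0.24), the hormone-like Pthlh (-2.53 ± 0.24), the stress gene Nupr1 (-2.38 ± 0.26), Egr1 (-2.35 ± 0.32) and Car12 (-2.34 ± 0.23) fell with them. The highest of the genes ranked was Pla2g5, 5.11-fold up at 20.9 ± 3.63 CPM (2.35 ± 0.43, adjusted p = 0.0138). The polarity gene Crb2 (1.46 ± 0.24), the developmental factor Zic2 (1.38 ± 0.22), the collagens Col9a2 (1.26 ± 0.14) and Col5a2 (1.05 ± 0.17) and AW551984 (1.16 ± 0.23) rose, with the adhesion receptor Gpr98 (1.05 ± 0.16), the spindle gene Tpx2 (1.03 ± 0.22) and the Notch target Hes1 (1.03 ± 0.14).

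Immediate early genes were lower at 2 months for 11 of 14 members (median -1.56, adjusted p = 1.49e-13, adjusted p = 0.0437 with an estimated correlation), among them Arc (-2.21 ± 0.20) and Junb (-1.51 ± 0.13). Medium spiny neuron genes were lower for 22 of 24 (median -1.30, adjusted p = 2.71e-27, adjusted p = 0.0793 with an estimated correlation). Pan-neuronal genes were lower for 10 of 24, and 17 over the list alone (median -0.70, adjusted p = 2.4e-12, adjusted p = 0.0437 with an estimated correlation), including the choline transporter Slc5a7 (-0.88 ± 0.09) and the neurofilament Nefm (-1.18 ± 0.15). Cholesterol genes were lower for 13 of 23 (median -0.69, adjusted p = 1.57e-13, adjusted p = 0.185 with an estimated correlation), with the sterol enzymes Msmo1 (-1.46 ± 0.18), Cyp51 (-1.26 ± 0.18) and Fdft1 (-1.10 ± 0.16). Oligodendrocyte genes had 3 of 20 lower and 8 over the list alone (median -0.85), such as the myelin gene Mobp (-1.24 ± 0.30). None of 30 astrocyte markers was called (median -0.10). The synapse-promoting Thbs1 rose (1.79 ± 0.25) while the matrix genes Hapln1 (-0.85 ± 0.12) and Vcan (-0.74 ± 0.18) fell. Rpl22, a ribosomal protein gene, stood at 531 ± 142 CPM in R6/2 against 1836 ± 724 in NCAR (-1.76 ± 0.27, adjusted p = 0.00569).

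Without NCAR replicate 2 the 2-month IP count was 2470, and it was 429, 456 and 492 without R6/2 replicates 4, 3 and 2 and 434 and 484 without NCAR replicates 4 and 1. With the pan-neuronal covariate, which differed between the genotypes in every library, the count was 0.

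In R6/2 IP RNA at 3 months 2136 of 15040 genes were called, 735 higher and 1401 lower. Among the genes ranked the 10 lowest were genes of interferon response, complement and antigen presentation, with a wide spread between NCAR libraries. Gbp8 fell to 5.02 ± 5.27 from 145 ± 144 CPM (-5.26 ± 0.88, adjusted p = 0.00536), and Iigp1 to 18.9 ± 11.8 from 442 ± 271 CPM (-4.56 ± 0.58, adjusted p = 0.00154). The GTPase genes Tgtp2 (-5.23 ± 0.77), Gbp2b (-4.98 ± 1.00) and Gbp4 (-4.54 ± 0.79), the complement genes C1s1 (-4.99 ± 1.27) and C1ra (-4.59 ± 0.77), the antigen presentation genes Cd74 (-4.52 ± 0.88) and H2-Ab1 (-4.49 ± 0.76) and the chemokine Cxcl10 (-4.49 ± 0.83) completed them. Zic2 rose most among them, 4.61-fold to 13.3 ± 3.61 CPM (2.21 ± 0.20, adjusted p = 0.000352). AW551984 (1.92 ± 0.23), Col9a2 (1.59 ± 0.17), Tpx2 (1.56 ± 0.23), the matrix gene Fbln2 (1.55 ± 0.18), the cell cycle inhibitor Cdkn1c (1.43 ± 0.24), the cyclase Gucy2f (1.42 ± 0.22), the protocadherin Pcdh20 (1.25 ± 0.21), Ttn (1.21 ± 0.30) and the lipase inhibitor Angptl4 (1.21 ± 0.22) followed.

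Interferon response genes were lower at 3 months for 12 of 15 members, 14 over the list alone (median -1.87, adjusted p = 7.85e-09, adjusted p = 0.237 with an estimated correlation), among them Gbp3 (-2.43 ± 0.33) and Ifitm3 (-2.25 ± 0.39). Of these 12 members 6 stayed called without NCAR replicate 4 and 8 without NCAR replicate 1. A1 reactive genes were lower for 10 of 12 (median -2.86, adjusted p = 3.68e-08, adjusted p = 0.159 with an estimated correlation), with the complement genes C3 (-4.05 ± 0.68) and Serping1 (-2.88 ± 0.49). Pan-reactive genes were lower for 8 of 13 (median -1.81, adjusted p = 3.96e-06, adjusted p = 0.243 with an estimated correlation), with the adhesion receptor Cd44 (-1.75 ± 0.28) and the iron-binding Lcn2 (-3.87 ± 0.68). Oligodendrocyte genes were lower for 11 of 20 (median -1.43, adjusted p = 4.66e-08, adjusted p = 0.237 with an estimated correlation), including the myelin genes Mal (-2.53 ± 0.33) and Mobp (-2.37 ± 0.35). Of 24 medium spiny neuron genes 22 were lower (median -1.19, adjusted p = 5.65e-19, adjusted p = 0.159 with an estimated correlation), with Scn4b at -3.23 ± 0.17.

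Cholesterol genes had 13 of 23 members lower at 3 months (median -0.68, adjusted p = 6.21e-11, adjusted p = 0.159 with an estimated correlation), with Msmo1 at -1.44 ± 0.13 and Fdft1 at -1.07 ± 0.11. Immediate early genes had 7 of 14 lower (median -0.94, adjusted p = 2.59e-05, adjusted p = 0.159 with an estimated correlation). Of 30 astrocyte markers 6 were lower and 2 higher (median -0.16, adjusted p = 0.142); the lower ones included the filament gene Gfap (-1.81 ± 0.36), Atp1b2 (-0.99 ± 0.18), Kcnj10 (-0.89 ± 0.18) and the water channel Aqp4 (-0.87 ± 0.19). The growth factor Bdnf was lower in the matrix list (-2.00 ± 0.25). Oxidative phosphorylation genes were higher as a list (median 0.28, adjusted p = 0.000163, adjusted p = 0.376 with an estimated correlation), with 1 of 26 called. Among chaperones the heat-shock genes Dnajb1 (0.61 ± 0.11) and Hspa5 (0.50 ± 0.11) rose and the small heat-shock genes Cryab (-1.15 ± 0.26) and Hspb8 (-0.69 ± 0.19) fell. The developmental factor Irx5 rose (2.52 ± 0.27).

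The 3-month IP count was 831 and 955 without NCAR replicates 4 and 1, 1068 and 1155 without R6/2 replicates 1 and 2, and 507 with an astrocyte marker covariate.

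**Figure D2:**
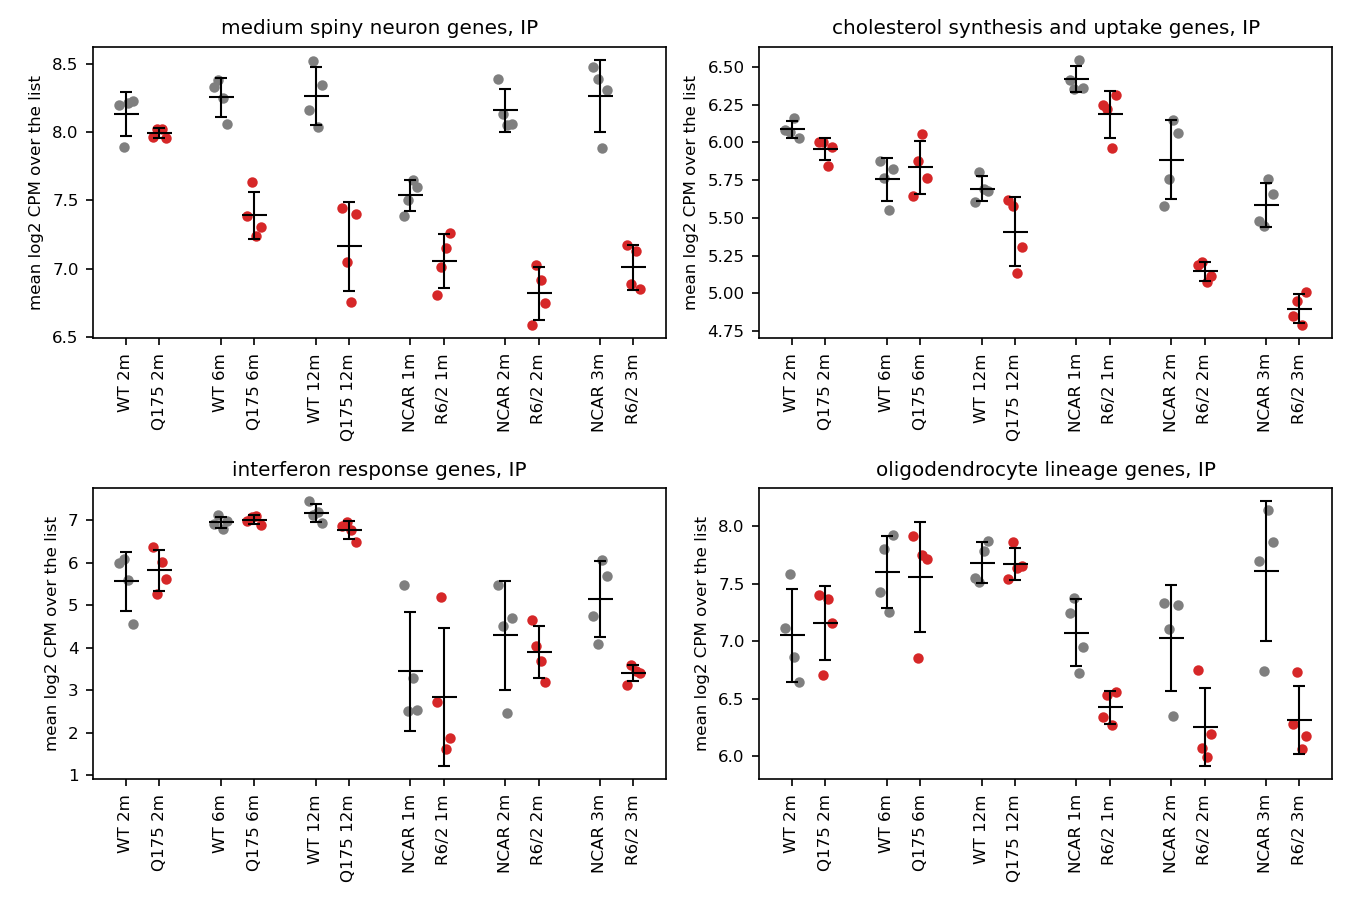
Mean log2 CPM over the members of 4 gene lists in each IP library, by genotype and age. Points are libraries, 4 per group, and bars are mean ± SD; interferon response genes stood at 5.14 ± 0.90 in NCAR and 3.39 ± 0.19 in R6/2 at 3 months.

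In Q175 a smaller share of IP-enriched genes than of other genes was called, 0.8% against 4.32% at 6 months and 4.44% against 7.41% at 12 months. Of 1980 IP-enriched genes tested 0 were called in limma at 2 months, 18 of 2237 (17 higher) at 6 months and 99 of 2229 (85 higher) at 12 months. Adjusted over these genes alone the calls were 0, 2 and 55, so most of the calls at 6 months were lost. At 6 months Zbtb7c (0.54 ± 0.09), Car8 (0.48 ± 0.08), the growth factor Tgfb2 (0.35 ± 0.06) and the calcium-binding S100a1 (0.33 ± 0.06) were higher and the retinoid enzyme Aldh1a1 was lower (-0.39 ± 0.09). At 12 months Tmc3, Thbs2, the collagen Col9a3 (0.81 ± 0.10), Fam181a (0.78 ± 0.20), the matrix gene Smoc1 (0.77 ± 0.08), Pcdh20 (0.75 ± 0.15) and Car8 (0.72 ± 0.11) were higher, and Isg15, the secreted Crispld2 (-0.71 ± 0.12), Insig1, Rsad2 and the cholesterol-esterifying Lcat (-0.52 ± 0.10) were lower.

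In R6/2 the IP-enriched calls were 2 of 2131 at 1 month (Foxj1 and Padi2, both lower), 107 of 2288 (52 higher) at 2 months and 416 of 2380 (85 higher) at 3 months. Adjusted over these genes alone the calls were 4, 72 and 476. Over all genes tested, the shares called were 0.09%, 4.68% and 17.48% of IP-enriched genes, against 0.08%, 5.77% and 13.59% of other genes. At 2 months Pla2g5, Crb2, Hes1, the Wnt inhibitor Sfrp1 (0.93 ± 0.11) and the lipid exporter Abca1 (0.87 ± 0.10) were higher, and Nupr1, the crosslinking enzyme Tgm1 (-2.15 ± 0.45), Rpl22, Msmo1 and the hormone Trh (-1.38 ± 0.25) were lower. At 3 months Fbln2, Gucy2f, Pcdh20, Angptl4 and the Notch target Hes5 (1.05 ± 0.25) were higher, and C1ra, Cxcl10, Tgm1 (-3.97 ± 0.68), Gbp5 (-3.75 ± 0.59), the checkpoint ligand Cd274 (-3.40 ± 0.44) and the amino acid transporter Slc1a5 (-3.30 ± 0.48) were lower. With a threshold of at least 0 or at least 2 for log2 IP over input, the counts were 52 and 2 in Q175 at 6 months, 247 and 21 at 12 months and 188 and 40 in R6/2 at 2 months.

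**Figure D3:**
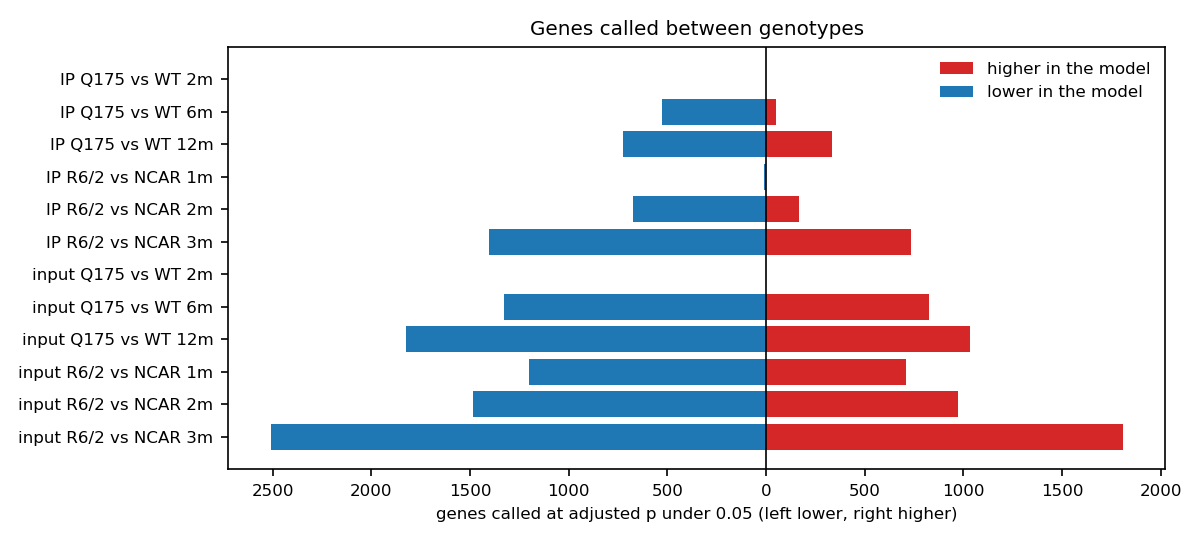
Number of genes called lower (left) and higher (right) in the disease model than in its control, for IP and input at each age, 4 libraries per group. Bars are genes at adjusted p under 0.05; R6/2 input at 3 months had 1808 higher and 2510 lower.

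In input RNA 1 of 15342 genes was called at 2 months in Q175, Abhd1 (8.16 ± 0.613 against 4.12 ± 0.590 CPM, 0.99 ± 0.12, adjusted p = 0.0421). Without any 1 of 7 of the 8 libraries, all but WT replicate 3, the count was 0, and 524 genes had an unadjusted p under 0.05 against 767 expected. Scaled as deposited it was 0 as well. Over the list alone 10 of 24 medium spiny neuron genes were lower (median -0.09, adjusted p = 1.6e-16, adjusted p = 0.213 with an estimated correlation).

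At 6 months 2154 of 15547 genes were called in Q175 input, 829 higher and 1325 lower. Sfmbt2 rose 3.62-fold to 16.5 ± 1.76 CPM (1.85 ± 0.10, adjusted p = 2.68e-06), followed by AW551984 (1.46 ± 0.19), Pcdh20 (1.33 ± 0.06), the retinoic acid pathway gene Greb1l (1.09 ± 0.14) and Chdh (1.04 ± 0.11). The transporter Slc4a11 fell to 1.51 ± 0.352 from 9.48 ± 2.88 CPM (-2.63 ± 0.22, adjusted p = 3.69e-05), with the lipid-binding Sec14l3 (-2.62 ± 0.15), the noncoding Abhd11os (-2.37 ± 0.09), Ryr1 (-2.23 ± 0.09) and the copine Cpne9 (-1.87 ± 0.20). Of medium spiny neuron genes 23 of 24 were lower (median -0.71, adjusted p = 1.7e-30, adjusted p = 0.153 with an estimated correlation), including the cannabinoid receptor Cnr1 (-1.17 ± 0.05). Calcium and receptor genes had 7 of 28 lower. Pan-neuronal genes had 4 members higher, such as the synaptic vesicle gene Syp (0.43 ± 0.06), and 1 lower, and their median of -0.04 and mean of 0.01 differ in sign, as do those of the A1 list (0.04 and -0.05) and the patterning list (-0.09 and 1.25). The count was 1349 without Q175 replicate 4 and 1417 without WT replicate 2. Scaled as deposited it was 3423 with 72.1% of calls higher against 38.5%, and the median of all genes was 0.10 against 0.02.

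At 12 months 2855 of 15555 genes were called in Q175 input, 1032 higher and 1823 lower. Nrn1, a neurite-promoting gene, rose 9.33-fold to 21.7 ± 2.92 CPM (3.22 ± 0.21, adjusted p = 1.69e-06). Sfmbt2 (2.14 ± 0.09), Pcdh20 (1.64 ± 0.11), the secreted Kazald1 (1.64 ± 0.14) and Rprm, a cell cycle arrest gene (1.28 ± 0.13), came next. Slc4a11 (-3.14 ± 0.20), Sec14l3 (-3.02 ± 0.23), Ryr1 (-2.73 ± 0.08, 15.4 ± 1.18 against 102 ± 9.32 CPM), the protease Tmprss6 (-2.69 ± 0.20) and Abhd11os (-2.41 ± 0.20) fell most of the genes ranked. The medium spiny neuron list was lower for 23 of 24 members (median -0.86, adjusted p = 5.89e-31, adjusted p = 0.137 with an estimated correlation). Of 30 astrocyte markers 10 were lower and 1 higher (median -0.15, adjusted p = 0.00685, adjusted p = 0.457 with an estimated correlation), with the bicarbonate transporter Slc4a4 at -0.54 ± 0.06 and the glutamine synthetase Glul at -0.35 ± 0.06. Patterning genes had 4 of 8 higher, including Pou4f1 (4.68 ± 0.43) and Irx5 (1.59 ± 0.39). Interferon genes had 5 of 15 lower, cholesterol genes 6 of 23 lower and immediate early genes 6 of 14 lower. Alas2, the heme enzyme of red cells, was lower (-1.36 ± 0.29). Scaled as deposited the count was 4405 with 72.6% of calls higher against 36.1%, and the median of all genes was 0.11 against 0.00.

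In R6/2 input 1910 of 15490 genes were called at 1 month, 711 higher and 1199 lower, against 12 in IP. Input and IP were not tested against each other at this age. Of simulated 1.5-fold changes 80.6% were called in input and 59.7% in IP. Slitrk6, a synaptic adhesion gene, rose 2.31-fold (1.21 ± 0.19, adjusted p = 0.00234), with Pcdh20 (1.17 ± 0.20), Ttn (1.13 ± 0.17), Fam196b (1.01 ± 0.15) and Tpx2 (0.97 ± 0.17). Abhd11os (-2.83 ± 0.27), Ryr1 (-2.39 ± 0.24, 29.4 ± 12.3 against 144 ± 10.9 CPM), the skin gene Dmkn (-1.95 ± 0.15), Ankrd35 (-1.66 ± 0.14) and Ace, the angiotensin-converting enzyme (-1.62 ± 0.27), fell most of the genes ranked. Among medium spiny neuron genes 23 of 24 were lower (median -0.75, adjusted p = 5.28e-28, adjusted p = 0.11 with an estimated correlation). Astrocyte markers were lower for 8 of 30 and 15 over the list alone (median -0.22), such as Slc6a11, a GABA transporter (-0.49 ± 0.09). The glucose list had a median of -0.02 and was not called (adjusted p = 0.97), and the patterning list a median of -0.30 and a mean of 0.16. The count was 1093 without R6/2 replicate 2 and 1100, 1106 and 1232 without NCAR replicates 2, 4 and 3.

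At 2 months 2455 of 15358 genes were called in R6/2 input, 972 higher and 1483 lower. Col5a2 rose 4.05-fold (2.02 ± 0.53, adjusted p = 0.0294), with Tpx2 (1.95 ± 0.26), AW551984 (1.78 ± 0.24), Ttn (1.71 ± 0.23) and Dleu7 (1.55 ± 0.29). Abhd11os fell to 0.849 ± 0.161 from 14.1 ± 0.769 CPM (-4.06 ± 0.18), with Egr2 (-3.91 ± 0.23), Ryr1 (-3.84 ± 0.13), Abi3bp (-3.52 ± 0.37) and the peptidase Phex (-2.91 ± 0.24). Medium spiny neuron genes were lower for 22 of 24 (median -1.29, adjusted p = 3.72e-25, adjusted p = 0.0039 with an estimated correlation) and immediate early genes for 10 of 14 (median -1.55, adjusted p = 2.19e-11, adjusted p = 0.0848 with an estimated correlation). Cholesterol genes were lower for 8 of 23 (median -0.36). The patterning list had a median of -0.01 and a mean of 1.01. Without R6/2 replicate 1 the count was 1616.

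At 3 months 4318 of 15368 genes were called in R6/2 input, 1808 higher and 2510 lower. The neuropeptide S receptor Npsr1 rose 11.5-fold to 9.24 ± 3.67 CPM (3.53 ± 0.60, adjusted p = 0.00187), with AW551984 (2.26 ± 0.19), the iodide transporter Slc5a5 (2.13 ± 0.37), Pcdh20 (2.05 ± 0.18) and Macrod1 (1.91 ± 0.18). The immune genes Ly6c2 (-6.71 ± 1.03), Pou2af1 (-5.60 ± 1.33), Gbp2b (-5.44 ± 0.90), Gbp8 (-5.09 ± 0.87) and Il2rb (-4.86 ± 0.84) fell most of the genes ranked. Microglia genes were lower for 13 of 15 (median -0.97, adjusted p = 6.9e-06, adjusted p = 0.286 with an estimated correlation), including the complement gene C1qb (-1.54 ± 0.30). A1 reactive genes were lower for 11 of 12 (median -2.40), interferon genes for 9 of 15 (median -1.49) and astrocyte markers for 16 of 30 with 1 higher (median -0.48, adjusted p = 6.77e-05, adjusted p = 0.269 with an estimated correlation). For medium spiny neuron genes 23 of 24 were lower (median -1.36, adjusted p = 8.94e-23, adjusted p = 0.00382 with an estimated correlation), with Scn4b at -3.16 ± 0.09. Without NCAR replicate 2 the count was 2877.

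**Figure D4:**
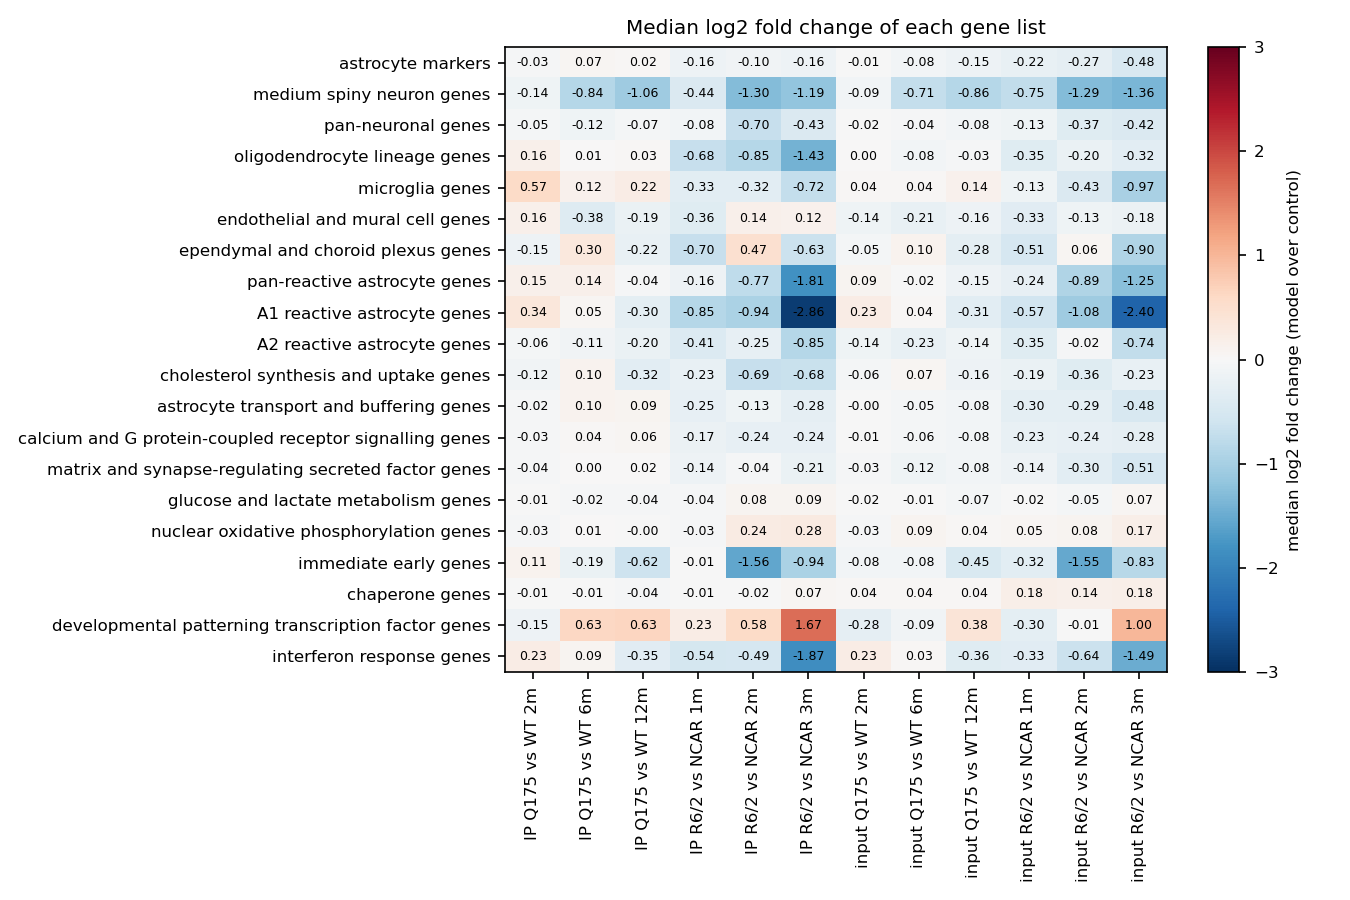
Median log2 fold change (model over control) of each gene list in the 12 genotype comparisons, colored from lower (blue) to higher (red). Each cell is 1 list in 1 comparison of 4 against 4 libraries; the A1 list stood at -2.86 in R6/2 IP at 3 months.

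IP and input changes were correlated across genes, least in Q175 at 2 months. At 12 months in Q175, 658 of the 725 genes lower in IP were also lower in input, where independent lists would share 86.7, and 193 of 333 higher genes were also higher in input (22.2 for independent lists). At 3 months in R6/2 the shared numbers were 1025 lower (217.9) and 493 higher (88.5), with 3 genes called in opposite directions. The Pearson correlation of log2 changes across genes was 0.22, 0.70 and 0.79 in Q175 at 2, 6 and 12 months and 0.56, 0.68 and 0.80 in R6/2 at 1, 2 and 3 months.

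Few genes were called as having a genotype change that differed between IP and input, in tests that called 46.3% (Q175) and 13.4% (R6/2) of simulated 1.5-fold differences. At an unadjusted p under 0.05 there were 924 genes in Q175 and 1221 in R6/2, against 782 expected in each. In Q175 at 12 months there were 19, 14 more positive in IP and 5 more negative. The stress-regulated Ddit4l differed most (1.51 ± 0.20, adjusted p = 0.00486), being 31.6 against 37.2 CPM in IP and 6.81 against 23.0 CPM in input. Abhd1 (1.24 ± 0.22), the growth factor Bmp7 (1.09 ± 0.17), the cytokine receptor Il17rc (0.84 ± 0.14) and the lipid enzyme Lpcat2 (0.81 ± 0.15) followed, and Sfmbt2 (-1.11 ± 0.15) and Rprm (-1.11 ± 0.18) were on the other side. The count was 10 without Q175 IP replicate 1, 11 without WT input replicate 3, and 12 without WT input replicate 1 or 2, Q175 input replicate 2 or WT IP replicate 4.

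In R6/2 at 3 months there were 24 such genes, 16 more positive in IP. Zic2 (1.64 ± 0.29, adjusted p = 0.0326), Trank1 (1.45 ± 0.22), Fam117a (1.34 ± 0.19), the adhesion gene Igsf21 (1.31 ± 0.20) and the neuropeptide receptor Npy2r (1.25 ± 0.22) were most positive. Echdc2 (-1.31 ± 0.23), Wbscr27 (-1.28 ± 0.24), Samd14 (-1.0 ± 0.18), the phosphatase Nudt4 (-0.78 ± 0.15) and Ppp1r26 (-0.76 ± 0.14) were most negative. The count was 128 without NCAR IP replicate 2, 40 without R6/2 input replicate 4, 15 without R6/2 IP replicate 1, 13 without R6/2 input replicate 1, 12 without NCAR IP replicate 1, R6/2 IP replicate 2, R6/2 input replicate 2 or NCAR input replicates 2 or 3, 10 without NCAR input replicate 4, and 9 without NCAR IP replicate 4 or R6/2 input replicate 3. Scaled as deposited, 53.8% of calls were higher against 66.7%.

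The genotype change in Q175 IP RNA differed between 12 and 2 months for 380 of 15296 genes, 79 more positive and 301 more negative. Ryr1 (-2.85 ± 0.17, adjusted p = 2.61e-07) stood at 64.1 against 59.2 CPM at 2 months and 6.58 against 43.9 CPM at 12 months. Abi3bp (-2.12 ± 0.24), Hrk (-2.02 ± 0.20), Scn4b (-1.94 ± 0.23) and Car12 (-1.83 ± 0.22) were the next most negative. Chdh (1.35 ± 0.30), Enpp6 (1.11 ± 0.24), the lipid transporter Abca8a (0.94 ± 0.17), Sfmbt2 (0.94 ± 0.15) and Col9a3 (0.89 ± 0.16) were most positive. The count was 203 and 230 without Q175 replicates 2 at 2 and 12 months, 204 and 208 without WT replicates 2 at the same ages, and 229 without WT replicate 4 at 12 months. Scaled as deposited 31.5% of calls were more positive against 20.8%. In R6/2 IP between 3 and 2 months 0 of 15260 genes were called by limma and 0 by voom, and 832 had an unadjusted p under 0.05 against 763 expected.

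Q175 at 12 months and R6/2 at 3 months shared many IP changes. Among 14847 genes tested in both, 717 and 1394 were lower in IP and 419 of them were lower in both, where independent lists would share 67.3, and 69 were higher in both (15.7, Fisher exact p = 2.96e-26), while 6 went in opposite directions. The Fisher test, here and in input below, treats genes as independent, so its p does not measure the spread between libraries. Across genes the Pearson correlation of log2 changes was 0.43 and the Spearman correlation 0.35. Ryr1 (-2.73 ± 0.10 and -3.53 ± 0.21), Hrk (-2.12 ± 0.14 and -2.18 ± 0.17), Scn4b (-2.16 ± 0.18 and -3.23 ± 0.17) and Car12 (-1.86 ± 0.18 and -2.28 ± 0.22) were lower in both. So were the peroxidase-like Gpx6 (-4.57 ± 0.43 and -4.19 ± 0.40), Ier5l (-0.89 ± 0.09 and -2.08 ± 0.21), Slc4a11 (-3.42 ± 0.20 and -3.33 ± 0.35), Rgs14 and Fam78a (-0.96 ± 0.10 and -1.68 ± 0.17). Nrn1 was higher in both (2.88 ± 0.24 and 2.63 ± 0.23). The rule on level and overlap left Gpx6, Slc4a11 and Nrn1 out of the genes ranked for Q175 IP at 12 months. The size of such changes can rest on few reads. Of 470 genes shared in direction, after passing over unnamed genes, 18 were IP-enriched in both. Those higher included Tmc3, Vat1, Fkbp14, Pcdh20, Gucy2f, Maged2, Wdr6, Fam83b, Chp2, Acot2 and Celrr, and those lower were Insig1, Crispld2, Rsad2, Ifit3, Cd274 and Lcat.

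**Figure D5:**
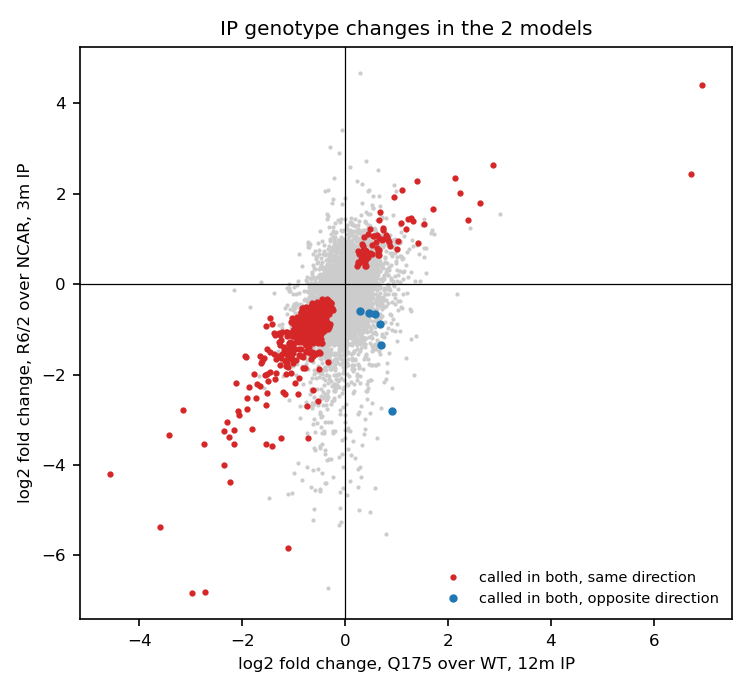
Log2 fold change in IP of each gene in Q175 at 12 months (horizontal) and R6/2 at 3 months (vertical), each from 4 against 4 libraries. Red points are genes called in the same direction in both (419 lower, 69 higher), blue points the 6 called in opposite directions, and gray points all others.

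In input the models shared 1204 lower genes (297.6 for independent lists) and 536 higher genes (119.4, Fisher exact p = 1.82e-249), with 34 in opposite directions. Scn4b (-1.83 ± 0.06 and -3.16 ± 0.09), Ryr1 (-2.73 ± 0.08 and -3.71 ± 0.15), Pde10a (-1.23 ± 0.07 and -2.28 ± 0.10), the adhesion gene Cntnap3 (-1.45 ± 0.07 and -2.17 ± 0.12), Cnr1 (-1.41 ± 0.06 and -1.95 ± 0.11) and Hrk (-1.88 ± 0.08 and -2.24 ± 0.13) came first by the larger of their adjusted p in the models. Car12, the integrin Itga9, the muscarinic receptor Chrm4 (-1.04 ± 0.07 and -1.55 ± 0.10) and Tbc1d8 (-0.82 ± 0.06 and -1.23 ± 0.08) followed. Within Q175 the IP calls at 6 and 12 months shared 412 lower genes (25.1) and 28 higher (1.1), and within R6/2 the IP calls at 2 and 3 months shared 489 lower (62.2) and 91 higher (8.2).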

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

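The tests of explanations for the interferon, medium spiny neuron and Abhd1 patterns were chosen only after those results were seen, as was the agreement of splits with other libraries, while the counts of genes called by splits were set before.

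A library stood far from the other 3 of its group in 12 of 216 groups of values, where chance alone gives about 1 in 20, or 10.8. A1 reactive astrocyte genes accounted for 4 of them, at a mean of 6.16 log2 CPM in 1 Q175 IP library at 6 months (others 6.69 to 6.76), 5.97 in 1 WT IP library at 6 months (6.69 to 6.74), 3.20 in 1 R6/2 input library at 1 month (1.89 to 2.01) and 2.54 in 1 NCAR IP library at 2 months (5.01 to 5.51). Htt stood at 206 CPM in 1 Q175 input library at 2 months (186.3 to 189.4) and at 371.3 CPM in 1 WT IP library at 6 months (389.2 to 392.3). Astrocyte markers stood at 9.47 in 1 Q175 IP library at 12 months (9.11 to 9.15) and at 7.12 in 1 WT input library at 12 months (7.098 to 7.101). Cholesterol genes stood at 4.75 in 1 WT input library at 12 months (4.87 to 4.88). Medium spiny neuron genes stood at 7.89 in 1 WT IP library at 2 months (8.20 to 8.23) and at 9.58 in 1 NCAR input library at 2 months (9.41 to 9.43). A single R6/2 input library at 2 months held 51.19 M reads (31.03 to 34.32 M).

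The genotype change differed between IP and input for 19 genes in Q175 at 12 months. On the side more positive in IP were Ddit4l (1.51), Abhd1 (1.24), Bmp7 (1.09), Il17rc (0.845) and Lpcat2 (0.805), and on the other Sfmbt2 (-1.11) and Rprm (-1.11). In R6/2 at 3 months it differed for 24 genes, with Zic2 (1.64), Trank1 (1.45), Fam117a (1.34), Igsf21 (1.31) and Npy2r (1.25) against Echdc2 (-1.31), Wbscr27 (-1.28), Samd14 (-1.0), Nudt4 (-0.777) and Ppp1r26 (-0.762). Between 12 and 2 months the genotype change in Q175 IP differed for 380 genes, with Chdh (1.35), Enpp6 (1.11), Abca8a (0.944), Sfmbt2 (0.94) and Col9a3 (0.888) against Ryr1 (-2.85), Abi3bp (-2.12), Hrk (-2.02), Scn4b (-1.94) and Car12 (-1.83).

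Splits of the same 8 libraries into 4 and 4 tested whether other divisions of them call as many genes. The smallest share possible is 1 of 35, and shares were not adjusted over the comparisons, so these splits alone cannot exclude chance. Only the real split, 1 of 35, gave as many genes in IP of Q175 at 2, 6 and 12 months. The counts were 3, 574 and 1059, and the highest other 0, 2 and 10. The count at 2 months rests on 3 genes, and 749 genes had an unadjusted p under 0.05 in limma against 752 expected. In IP of R6/2 at 1 and 3 months the real split alone gave as many too (1 of 35 splits each, 12 and 2136 genes, highest other 3 and 1767). The split with 1767 exchanges NCAR replicate 3 for R6/2 replicate 3, and without that NCAR library the count was 3133, so it points to a structure of the samples. For IP of R6/2 at 2 months 2 of 35 splits gave as many, 842 for the real split and 3044 for R6/2 replicate 1 with NCAR replicates 1, 3 and 4. The share is 2 of 35, so the count alone does not exclude chance there. The calls shared with separate libraries argue against chance as the whole cause, since 580 were shared in sign with R6/2 IP at 3 months (highest other split 403) and 400 with Q175 IP at 12 months (highest other 64), each reached by 1 of 35 splits. The correlation with R6/2 IP at 3 months (0.658) decides nothing, as another split gave 0.696. The split with 3044 genes points to a structure of the samples, since NCAR replicate 2 is on the side of 3 R6/2 libraries, with ependymal genes at 3.22 against 1.09 to 1.67 and oxidative phosphorylation genes at 7.85 against 7.19 to 7.46 in the other NCAR libraries.

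In input, 3 of 35 splits gave as many genes for Q175 at 2 months (1 gene, highest other 309), so the count alone does not exclude chance. The gene is Abhd1, which was also called higher in the separate input libraries at 6 and 12 months (0.765 and 0.939), and this argues against chance for Abhd1. The highest split (WT replicates 1 and 2 with Q175 replicates 1 and 4) points to a structure of the samples apart from genotype. At 6 and 12 months in Q175 only the real split, 1 of 35, gave as many (2154 and 2855 genes, highest other 309 and 47). The same held in R6/2 at 1, 2 and 3 months (1910, 2455 and 4318 genes, highest other 2, 2164 and 1). The split with 2164 genes (R6/2 replicates 1 and 3 with NCAR replicates 1 and 3) points to a structure of the 2-month input libraries apart from genotype. For IP against input the real split alone, 1 of 35, gave as many in WT (12250, 11935 and 11974 genes, highest other 0, 0 and 0 by limma). In NCAR it did as well (11146, 8554 and 8715, highest other 2, 1 and 4). For the interactions genotype labels were exchanged within each RNA type or age in 100 splits. For genotype by RNA type 4 of 100 gave as many genes in Q175 (19, highest other 980) and 5 of 100 in R6/2 (24, highest other 2267). For genotype by age 6 of 100 did in Q175 (380, highest other 926) and 100 of 100 in R6/2, where the real count was 0 and the share was fixed (highest other 140). These splits say nothing on chance, because mixing 1 RNA type or age turns the genotype effect of the other into a difference. The structure behind the high counts includes genotype itself, since the highest splits of both age tests put all 4 control libraries of the older age in the place of the model.

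Interferon response genes were lower in R6/2 IP at 3 months for 12 of 15 members. Without NCAR replicate 4 the called members were 6, without replicate 1 they were 8 and without replicate 2 or 3 they were 12. Medians over the 12 members were -1.70 to -2.29. These members were chosen as called lower with all libraries, so the sign was nearly fixed and decides nothing on 1 control library. Without replicate 4 the calls over all genes fell too, from 2136 to 831. The fewer called members are thus not particular to this list. A bound written after the result was seen, at most 6 called members left without 1 NCAR library, was met with replicate 4. Dependence of part of the calls on that library is therefore not argued against. Dependence particular to this list cannot be told from the fall over all genes. The list stood above input in NCAR IP (median 1.61, SE 0.196 over genes and not libraries). Microglia genes stood far below (-4.87), which argues against RNA of microglia as the main source. Other immune cells had no list and were not tested. Immune genes such as Ly6c2, Pou2af1 and Il2rb were lower in R6/2 input at this age. Called members were 0, 0 and 12 at 1, 2 and 3 months, but the genotype by age test of 3 against 2 months called 0 genes in limma and 0 by voom (832 at an unadjusted p under 0.05), so a difference between these ages was not shown. An effect of genotype stays open.

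Medium spiny neuron genes were lower in IP in both models. In WT at 12 months their median IP over input was -0.85, beside -4.67 for microglia genes and -2.72 for endothelial and mural genes. Carry-over of whole striatum RNA in equal proportion would bring these lists along alike. The values argue against it as the main source of medium spiny neuron RNA in that IP. Carry-over that is uneven between cell types cannot be told apart from a change in the IP cells. In either genotype by RNA type test 0 of 24 members were called by limma, but at 1.5-fold these tests called 46.3% and 13.4% of simulated differences, and the median of IP minus input changes was -0.261 (SD 0.168) in Q175 and 0.133 (SD 0.16) in R6/2. In Q175 IP at 12 months the pan-neuronal median was -0.068 (SE 0.054) beside -1.06 (SE 0.081) for medium spiny neuron genes. These SE are over the genes of a list and do not measure the spread between libraries. The pan-neuronal list holds general neuronal genes and genes of single neuron types, such as Sst, Npy, Pvalb, Chat, Slc5a7 and Nos1. The medians argue against a fall shared equally by the RNA of all neurons in the Q175 IP. They cannot tell a lower share of medium spiny neuron RNA alone from a change inside cells. A fall shared by all neurons is not argued against in R6/2 IP at 2 months, where pan-neuronal genes fell too (median -0.70 beside -1.30). A change with genotype inside the cells that gave the IP RNA stays open, as untested.

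Abhd1 was higher in IP and input of Q175 at each age. It lies 3.81 Mb from Htt, and DNA next to the altered Htt gene is a candidate cause that these values do not argue against. In R6/2, where Htt is not the altered locus, Abhd1 was not called by limma (adjusted p = 0.559 to 0.915). Its spread there was wide, with IP changes of 0.598 ± 0.686, -0.079 ± 0.388 and -0.221 ± 0.875 at 1, 2 and 3 months. In IP at 3 months single libraries held 2.749 to 21.8 CPM in NCAR and 2.112 to 20.99 CPM in R6/2. The missing call therefore shows little, and the cause of this spread within a genotype was not tested. With Abhd1 left out, 11 of 146 genes within 10 Mb of Htt were called in Q175 IP at 12 months against 1042 of 14891 others, and 29 of 149 in input against 2807 of 15237, where an excess was not found (one-sided Fisher exact p = 0.446 and 0.405). An effect of the Htt change on Abhd1 stays open, as untested.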

How the results depend on the processing

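The values scaled as deposited, the prior count of 2 and the astrocyte marker covariate were chosen only after the data were seen, and all other alternatives before. No paired analysis was possible because the labels number libraries through the whole series and tie no library of 1 group to a library of another. A DESeq2 count test was not run on the recovered reads, and a sex covariate was not run because Xist was not in the tables used here. The cause of results that did not hold was not tested.

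Over the named genes, 14964 of 15967 values under an alternative kept direction and call, 984 kept direction and lost the call, and 19 changed sign. Of these 19, 9 came from leaving out 1 library, 9 from the pan-neuronal covariate and 1 from the astrocyte covariate. A prior count of 2, median-of-ratios factors, no filter on low counts, voom and the deposited scaling turned no named gene.

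With an adjusted p under 0.10 the IP counts were 900 in Q175 at 6 months (574 at 0.05) and 1757 at 12 (1059), and 45 (12), 1580 (842) and 3559 (2136) in R6/2 at 1, 2 and 3 months. In input they were 2 (1) in Q175 at 2 months and 2985 (1910) in R6/2 at 1 month. Genotype by RNA type gave 50 genes in R6/2 (24), genotype by age 703 in Q175 (380), and the overlap of IP calls between models 797 genes (488). With all ages in 1 fit Q175 IP gave 8 genes at 2 months (3) and 1865 at 12 (1059). Voom gave 7 in R6/2 IP at 1 month (12). Scaled as deposited, Q175 input gave 0 genes by limma at 2 months (1), 3423 at 6 (2154) and 4405 at 12 (2855).

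With the pan-neuronal covariate the IP count was 243 in Q175 at 6 months (574), 19 in R6/2 at 1 month (12) and 0 by limma at 2 months (842). At 2 months Crb2 (-0.513), Fam69c (-0.60) and Bdh2 (-0.757) turned lower and Htt (0.267), Atp2b2 (0.156), Chrdl1 (0.661), Vcan (0.283), Plekhd1 (0.679) and Hmgcs1 (0.408) turned higher. The list mean was 7.18 to 7.37 in R6/2 and 7.76 to 8.03 in NCAR there, so that this fit cannot separate genotype from the covariate. With the astrocyte covariate the count was 1720 in Q175 at 12 months (1059), 0 by limma in R6/2 at 1 month (12) and 507 at 3 months (2136), and Htt stood at -0.286 in R6/2 at 3 months.

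For IP-enriched genes, a log2 IP over input of at least 0 gave 1, 52 and 247 calls in Q175 at 2, 6 and 12 months and 4, 188 and 743 in R6/2 at 1, 2 and 3 months, and at least 2 gave 2 and 21 in Q175 at 6 and 12 months and 1, 40 and 1.8e2 (rounded) in R6/2, beside 0, 18, 99, 2, 107 and 416 at the threshold of 1.

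Camera with an estimated correlation called far fewer lists over the 18 comparisons. Astrocyte markers went from 12 to 3 calls, medium spiny neuron genes from 18 to 2, pan-neuronal from 9 to 1, endothelial from 12 to 1, transport from 11 to 3, calcium and receptor from 15 to 1, matrix from 10 to 2 and immediate early from 6 to 1. Oligodendrocyte (9), microglia (13), ependymal (5), pan-reactive (9), A1 (6), A2 (4), cholesterol (16), glucose (6), oxidative phosphorylation (6), chaperone (6), patterning (4) and interferon genes (10) went to 0.

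Leaving out 1 library, the IP counts ran from 1 to 7, 305 to 828 and 460 to 1026 in Q175 at 2, 6 and 12 months and from 2 to 34, 429 to 2470 and 831 to 3133 in R6/2 at 1, 2 and 3 months. The input counts ran from 0 to 1, 1349 to 2113 and 2058 to 2556 in Q175 and from 1093 to 2029, 1616 to 2449 and 2877 to 5172 in R6/2. IP against input gave 11898 to 12067, 11473 to 11771 and 11563 to 11829 in WT and 10514 to 11717, 7475 to 8758 and 7774 to 9221 in NCAR. Genotype by RNA type gave 10 to 19 in Q175 and 9 to 128 in R6/2, and genotype by age 203 to 495 in Q175 and 0 to 0 by limma in R6/2. Htt, not called in R6/2, ran from -0.107 to 0.125 in IP at 2 months, -0.042 to 0.293 in IP at 3 months, -0.039 to 0.018 in input at 1 month, -0.041 to 0.312 for genotype by age, and in NCAR at 1 month from -0.015 to 0.110 for IP against input.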

Other observations

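All genes in this part were chosen only after their values were seen.

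The neuronal genes Chat, Slc5a7 and Nos1 were lower in R6/2 input at each age. Chat, the acetylcholine enzyme, stood in input at -0.43 ± 0.10, -1.26 ± 0.12 and -1.55 ± 0.12 at 1, 2 and 3 months, 12.1 against 35.5 CPM at the last age, with 4 libraries per group. Slc5a7, the choline transporter, stood at -0.28 ± 0.07, -1.28 ± 0.14 and -1.58 ± 0.15, and Nos1, the nitric oxide synthase, at -0.48 ± 0.08, -1.26 ± 0.13 and -1.60 ± 0.18. In IP Chat fell by 0.76 ± 0.11 at 2 months and 1.04 ± 0.12 at 3 months, and Slc5a7 by 0.88 ± 0.09 and 1.06 ± 0.13. Q175 input at 12 months had Chat at -0.33 ± 0.07 and Slc5a7 at -0.29 ± 0.06, both called, and neither was called in Q175 IP. No list of the cells that use these 3 genes was tested.

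In input some neuronal and glial genes changed with the same sign in both models. Stmn2, a growth-related tubulin regulator, rose by 0.69 ± 0.06 and 0.74 ± 0.08 in Q175 at 6 and 12 months and by 0.65 ± 0.07, 0.66 ± 0.15 and 0.78 ± 0.09 in R6/2 at 1, 2 and 3 months. Syp, a synaptic vesicle gene, was at 0.56 ± 0.06 in Q175 at 12 months and 0.73 ± 0.14 in R6/2 at 3 months. Slc4a4, the bicarbonate transporter of astrocytes, fell by 0.42 ± 0.04 and 0.54 ± 0.06 in Q175 and by 0.46 ± 0.07, 0.68 ± 0.13 and 0.81 ± 0.11 in R6/2 at the same ages. S100b, a calcium-binding gene of astrocytes, was higher in Q175 (0.41 ± 0.07 and 0.46 ± 0.11) and in R6/2 at 2 and 3 months (0.47 ± 0.12 and 0.72 ± 0.11). Hspb8, a small heat-shock gene, fell in Q175 at 12 months (-0.35 ± 0.08), was not called at 6 months, and fell in R6/2 at each age (-0.43 ± 0.09, -0.70 ± 0.14 and -1.09 ± 0.12). Stmn2, Syp and Slc4a4 were not called in IP in any comparison, nor in a genotype by RNA type test, so that IP and input were not shown to differ for them. Fbln5, an elastic fiber gene, was lower in IP as well, at -0.83 ± 0.14 and -0.89 ± 0.20 in Q175 at 6 and 12 months and -1.02 ± 0.24 and -1.28 ± 0.24 in R6/2 at 2 and 3 months.

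The reads of Rpl22, a gene of the large ribosomal subunit, were far more frequent in IP than in input and varied between libraries. With 1 scaling per run it stood in IP at 3102 ± 1622, 2030 ± 777 and 1045 ± 379 CPM in NCAR at 1, 2 and 3 months and at 2948 ± 1277, 584 ± 153 and 330 ± 95.4 in R6/2. In WT it stood at 1105 ± 211, 967 ± 280 and 774 ± 179 CPM at 2, 6 and 12 months and in Q175 at 1166 ± 326, 665 ± 122 and 434 ± 213. Input levels were 131 to 354 CPM. The labels name no tag for the IP, and what Rpl22 reads stand for was not tested.

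Interferon response genes in control IP RNA stood at different levels in the groups. Their mean was 5.56 ± 0.70, 6.95 ± 0.14 and 7.18 ± 0.22 log2 CPM in WT at 2, 6 and 12 months and 3.44 ± 1.40, 4.29 ± 1.29 and 5.14 ± 0.90 in NCAR at 1, 2 and 3 months. Ages were not tested against each other in controls, and the 1-month libraries carry another run label. NCAR IP replicate 3 at 3 months was highest of its group in interferon genes (6.06) and microglia genes (2.50).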
